A study of Mus musculus with 24 samples.

How the data were processed

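Libraries of poly(A) RNA came from bone marrow-derived macrophages of 6 mice, with total and ribosome-bound (TRAP) RNA taken from the same lysates after 18 h at 20% or 1% oxygen, per the labels. The deposited tables held TPM, with 52636 genes in each file, total RNA in the first file and TRAP RNA in the second. TPM, the unit deposited, is by definition scaled to gene length and to the total of each library, and each column summed to between 999629 and 999969, so no read depth and no counting interval could be given. HISAT, DESeq2 and the genome build GRCm38 are named per the submitters' processing notes, and their versions and settings are not given in the sources used here. Gene symbols and coordinates came from GENCODE M21 on GRCm38, matched by Ensembl identifier, with 233 identifiers not matched. Of the deposited gene symbols 27 were written as dates, and these genes were named through their identifiers. Whether reads were assigned by strand is not stated, so overlapping antisense genes could not be told apart.

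Samples were grouped by genotype, oxygen and fraction into 8 groups of 3. The same mouse number in the labels marks the same animal. Deviations from the group means correlated between the normoxic and hypoxic library of a mouse at 0.565 to 0.795 in total RNA and 0.397 to 0.717 in TRAP RNA, so mouse numbers pair the samples. No pair of columns was identical. The Y-linked gene Eif2s3y was near 0 in mice HET-102 and KO-281, 1 of each genotype, so each genotype held both sexes.

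The groups, tests, gene lists, naming rule and first set of alternatives were chosen before the data were examined. Count-based tests planned for that case could not be run on TPM, and the planned substitute for normalised values was used. Values were transformed to log2(TPM + 1), genes with at least 1 TPM in 3 of the libraries fitted were kept, and linear models with empirical Bayes moderation and a mean-variance trend (limma-trend) were fitted in R 4.3.3 with limma 3.58.1, with files read by version 1.17.8 of the data.table package. Total and TRAP RNA were fitted apart, each with 4 groups of 3 and 12 libraries sharing a variance, except that comparisons across fractions used all 24. Adjusted p are Benjamini-Hochberg values over all genes tested in a comparison, two-sided, with a threshold of 0.05. Error terms are SD for TPM and SE for log2 differences. The 15 planned comparisons had no mouse block in the planned fit, and the block was an alternative to it set at the same time. After the planned fits of hypoxia against normoxia gave no calls, 3 comparisons were added over all 6 mice with the mouse as a block, and planned, blocked and added fits are all given. For the added comparisons the naming rule's demand that groups not overlap was replaced by the same direction in 6 of 6 mice, a choice made after the data were seen.

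A set of 30 gene lists was tested with camera, with the correlation between genes estimated for each list, for lists with at least 5 tested genes, and with adjustment over the lists of a comparison. Camera's adjusted p are given as such. Camera with a preset correlation of 0.01 and fry were alternatives. Over the added total RNA comparison 0 lists passed with the estimated correlation, 10 with the preset one and 6 with fry.

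Genes were named by a fixed rule. Elavl1 was always named. Otherwise genes past the threshold with a mean of at least 4 TPM and groups that did not overlap were named, 8 in each direction for hypoxia and genotype comparisons and 4 for the others, and 2 to 4 members of each list described. Results of some single list members are not reported here. Genes known only by a clone or Gm name and pseudogenes were counted but not named by this rule.

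Models were tested on simulated data with 200 changed genes. In the control hypoxia comparison in total RNA on 12169 genes, the fit without a block found 34 of 100 genes changed by a log2 of 1 and 87 of 100 changed by 2, with 1 false call, and the blocked fit found 70 and 94 with 4. The fit over 6 mice found 84 and 99 with 10 false calls. The genotype comparison in normoxic total RNA on 12189 genes found 30 and 68 with 24 false calls. Libraries of a mouse are correlated while this fit treats them as independent, and the part this plays was not tested apart. With only the 6 libraries compared, on 11737 genes, it found 7 and 46 with 3 false calls. In TRAP RNA on 11407 genes the control hypoxia fit found 9 and 59 with 0 false calls, 32 and 80 with 3 when blocked, and the fit over 6 mice found 64 and 90 with 15. The genotype comparison in TRAP RNA on 11402 genes found 16 and 62 with 12 false calls, and on 10840 genes with the 6 libraries compared 0 and 19 with 0. Adjusted p of the genotype fits with 12 libraries were thus too small in these simulations. Simulated mouse effects were drawn gene by gene and lack profiles shared by many genes, as in mice HET-129 and KO-301. In the real fits 5.64, 3.47, 3.06 and 3.69% of genes had an unadjusted p under 0.05 (normoxic total, hypoxic total, normoxic TRAP and hypoxic TRAP RNA). Whether the real adjusted p are too small was therefore not settled.

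Alternatives were quantile normalization, no filter on low values, a pseudocount of 0.1, only the groups compared, the mouse block or its removal, and each mouse left out. The comparisons of genotype were also run without genes of the X and Y chromosomes. Added after the data were seen were rescaling to the sum of 21714 nuclear protein-coding genes other than ribosomal proteins, and leaving out mice HET-129 and KO-301 together. Agreement between fractions was set against 10 splits with swapped oxygen labels, also after the data were seen. Merged exon lengths came from the same annotation. Not used here were 24 further columns given per mouse and 6 columns of means and standard deviations.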

Results

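Messenger RNA was measured in cultured macrophages grown from the bone marrow of 6 mice. Mice are named by the genotype prefix and animal number of their labels. Mice HET-97, HET-102 and HET-129 were controls that carried 1 floxed and 1 intact copy of Elavl1, and mice KO-176, KO-281 and KO-301 were labelled as knockouts with both copies floxed. All carried a Cre recombinase driven by the Csf1r promoter, which acts in macrophages. Elavl1 encodes HuR, a protein that binds AU-rich stretches in the 3' untranslated regions of many messenger RNAs. Cells from each mouse were held for 18 h at 20% or at 1% oxygen. Each lysate gave a total RNA library and a library of ribosome-bound RNA, obtained by translating ribosome affinity purification (TRAP) through the tagged ribosomal protein L10a. The 24 libraries formed 8 groups of 3, and each mouse appeared in 4 of them. Values were TPM, the share of transcripts that each gene takes in its library, so the sequencing depth of each library was unknown. A gene rule of 1 TPM in 3 libraries left 12403 genes in total RNA and 11676 in TRAP RNA.

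Elavl1, the targeted gene, was not lower in total RNA of the labelled knockouts. The gene (ENSMUSG00000040028.10, chromosome 8, 4285382 to 4325413, minus strand, GRCm38) stood at 32.1 ± 3.15 TPM in normoxic controls and at 35.3 ± 0.664 TPM in normoxic labelled knockouts (SD, n = 3). In hypoxia the values were 35.3 ± 21.3 and 30.1 ± 4.43 TPM, with control mouse HET-102 alone at 59.8 TPM. The difference on the log2 scale was 0.14 ± 0.31 (SE) in normoxia with a limma adjusted p of 0.933, and -0.08 ± 0.31 in hypoxia with an adjusted p of 0.994. In TRAP RNA, Elavl1 stood at 18.1, 16.8 and 12.2 TPM in normoxic controls and at 17.4, 17.7 and 0.840 TPM in normoxic labelled knockouts KO-176, KO-281 and KO-301. Under hypoxia the TRAP values were 17.2, 16.3 and 10.5 TPM in controls and 1.75, 23.5 and 12.2 TPM in labelled knockouts. The TRAP differences of -0.94 ± 0.90 and -0.68 ± 0.90 did not pass, with adjusted p of 0.9997 and 0.999. A value for the whole gene does not test whether an exon was deleted, since a shortened transcript still gives reads. Genotypes are therefore written as labelled, and each genotype direction rests on those labels.

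**Figure D1:**
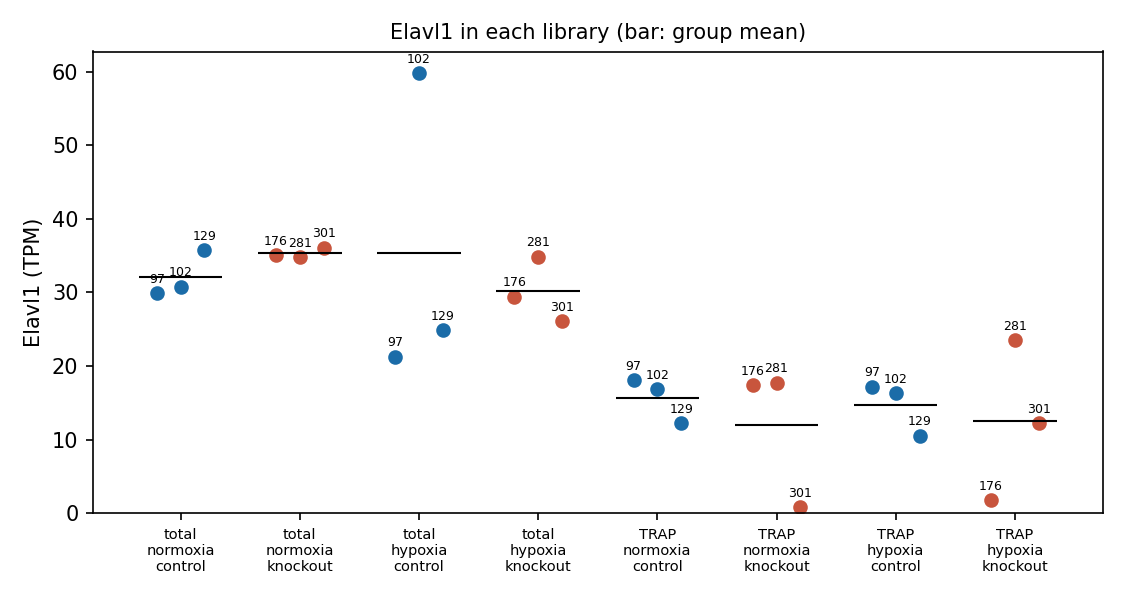
Elavl1 in TPM (y axis) for each of the 24 libraries in the 8 groups (x axis), with mouse numbers beside the points and bars at the group means. Normoxic total RNA of controls (29.9 to 35.7 TPM) and labelled knockouts (34.8 to 36.1 TPM) overlapped, and 1 TRAP library of mouse KO-301 stood at 0.840 TPM.

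Hypoxia raised Arg1 and lowered Tfrc in control macrophages once each mouse was compared with itself. Arg1 encodes arginase 1, which consumes arginine and is induced by hypoxia-inducible factors. Its total RNA was 14.9 ± 6.99 TPM in normoxia and 114.9 ± 70.1 TPM in hypoxia in controls (SD, n = 3). Tfrc, the transferrin receptor that brings iron into the cell, went from 61.4 ± 23.7 to 14.4 ± 5.46 TPM. With the mouse as a block, limma called 3 genes up, Arg1 (log2 change 2.77 ± 0.16, adjusted p 0.00826), Bnip3 (1.20 ± 0.11, adjusted p 0.0403) and Pgk1 (0.83 ± 0.06, adjusted p 0.00901). The same fit called 2 genes down, Tfrc (-2.02 ± 0.13, adjusted p 0.00826) and Tnf (-1.16 ± 0.08, adjusted p 0.00965). Bnip3, a mitophagy receptor, and Pgk1, a glycolytic kinase, are targets of the same factors. Without the block, the planned limma fit made 0 calls in 12403 genes, with 308 at an unadjusted p under 0.05 against 1625 with the block. Leaving out mouse HET-97 gave 1 call in the planned fit, and leaving out any other mouse gave 0.

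In labelled knockout macrophages, hypoxia lowered Tfrc from 32.7 ± 16.9 to 8.53 ± 3.09 TPM (n = 3) when the mouse was a block. The blocked limma fit called this gene (-1.75, adjusted p 0.0205) together with rises of Pum2 (1.29 ± 0.08, adjusted p 0.0128) and Pgk1 (0.66, adjusted p 0.0394). After rescaling the blocked fit called 1 gene higher and 1 lower, and single mice were not left out of the blocked fits within a genotype. Pum2, a Pumilio protein that represses messenger RNAs through their 3' ends, stood at 19.5 ± 2.19 TPM in normoxia and 49.2 ± 6.89 TPM in hypoxia. In controls the Pum2 values were 48.9 ± 22.5 and 44.6 ± 20.0 TPM. The planned fit without the block made 0 calls, with 398 genes at an unadjusted p under 0.05 against 1969 with the block, and 2 calls without mouse KO-281. In TRAP RNA neither genotype gave a call in limma, with 258 and 289 genes at an unadjusted p under 0.05 (942 and 1036 with the block) in controls and labelled knockouts. Leaving out mouse KO-176 gave 1 call in TRAP RNA of labelled knockouts. Glycolytic genes as a list stood higher in TRAP RNA of hypoxic controls (21 of 22 genes, median log2 change 0.58, camera adjusted p 0.0204), with Eno1 at 0.91 ± 0.23 and Pgk1 at 0.96 ± 0.25. No member passed over all genes and 2 did when adjusted over the list alone. Leaving out any 1 of the 6 mice ended this list call, at adjusted p of 0.0645 without mouse HET-97, 0.0613 without HET-102, 0.0518 without HET-129, 0.0592 without KO-176, 0.102 without KO-281 and 0.0963 without KO-301. The mouse block ended it as well (0.154), and over its alternatives the adjusted p ran from 0.00567 to 0.331.

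Across all 6 mice, hypoxia changed single genes in total RNA in both directions, and 0 lists passed. This comparison, 1 oxygen effect over both genotypes with each mouse as its own control, was added after the planned fits of hypoxia against normoxia gave no calls. Egln3, a prolyl hydroxylase that marks hypoxia-inducible factors for decay, went from 16.8 ± 9.89 to 63.5 ± 21.8 TPM (SD, n = 6) and rose by 2.02 ± 0.19 (limma adjusted p 0.00826). Arg1 (chromosome 10, 24915221 to 24927484) went from 16.1 ± 9.92 to 86.3 ± 60.7 TPM and rose by 2.20 ± 0.23 (adjusted p 0.00997). Ankrd37 rose by 1.59 ± 0.17, the adenylate kinase Ak4 by 1.26 ± 0.15 and Bnip3 by 0.97 ± 0.11, with adjusted p of 0.00997, 0.0101 and 0.00997. The lactate exporter Slc16a3 (61.8 to 159.0 TPM), the glycolytic isomerase Gpi1 (438.8 to 924.1 TPM) and the signalling adaptor Arrb1 (3.93 to 22.2 TPM) also rose, by 1.43 ± 0.26, 1.12 ± 0.18 and 1.81 ± 0.39. Each of these 8 genes was higher in 6 of 6 mice, as the naming rule demanded. The same direction in 6 of 6 mice, up or down, held for 16.2% of all genes tested. Limma called 194 genes up and 298 down of 12403, with 2805 at an unadjusted p under 0.05. Quantile normalization, which gives every library the same distribution of values, called 269 up and 260 down, and 418 of its calls were shared. Without the mouse block the same contrast gave 0 calls. Leaving out 1 mouse lowered the number of calls to 65 without mouse HET-97, 48 without HET-102, 93 without HET-129, 54 without KO-176, 224 without KO-281 and 140 without KO-301. Arg1, Egln3, Ankrd37, Ak4 and Bnip3 stayed past the threshold in all 6 of these fits, with adjusted p of at most 0.0488. Without mice HET-129 and KO-301 together, which leaves fewer mice, 4 genes were called up and 4 down. Egln3 kept its call there, and Arg1, Ankrd37, Ak4 and Bnip3 lost theirs. Arrb1 lost its call without any mouse but KO-281 (adjusted p up to 0.122), Slc16a3 without any but HET-97 (up to 0.0983), and Gpi1 without HET-97, HET-102, HET-129 or KO-176 (up to 0.0734).

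Tfrc (chromosome 16, 32608920 to 32632794) led the named falls, from 47.1 ± 24.3 to 11.4 ± 5.09 TPM, a log2 change of -1.88 ± 0.10 (SE, n = 6, limma adjusted p 0.000822). Id1 and Id3, which block basic helix-loop-helix transcription factors, fell from 35.8 ± 20.7 to 14.4 ± 9.10 TPM and from 43.8 ± 22.6 to 16.01 ± 13.3 TPM. Their log2 changes were -1.26 ± 0.09 and -1.65 ± 0.30, with adjusted p of 0.00451 and 0.0318. The nuclear long noncoding RNA Malat1 fell by 1.16 ± 0.10 (adjusted p 0.00793) and the stress kinase gene Plk3 by 1.09 ± 0.13 (adjusted p 0.0102). Chac1, a glutathione-degrading enzyme, fell by 1.18 ± 0.23, the vesicle regulator Rab6a by 1.11 ± 0.24, and the neutrophil-attracting chemokine Cxcl2 by 1.00 ± 0.18. Their adjusted p were 0.0393, 0.0463 and 0.0326. These 8 genes were lower in 6 of 6 mice, as the naming rule demanded. Tfrc, Id1 and Malat1 stayed past the threshold whichever mouse was left out, with adjusted p of at most 0.0474. Without mice HET-129 and KO-301 together, Tfrc and Malat1 kept their calls and Id1 lost its call. Plk3 lost its call without mouse HET-102 (0.0512), Rab6a without any mouse (0.0687 to 0.118), and Id3, Chac1 and Cxcl2 without any mouse but KO-281 (up to 0.102).

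**Figure D2:**
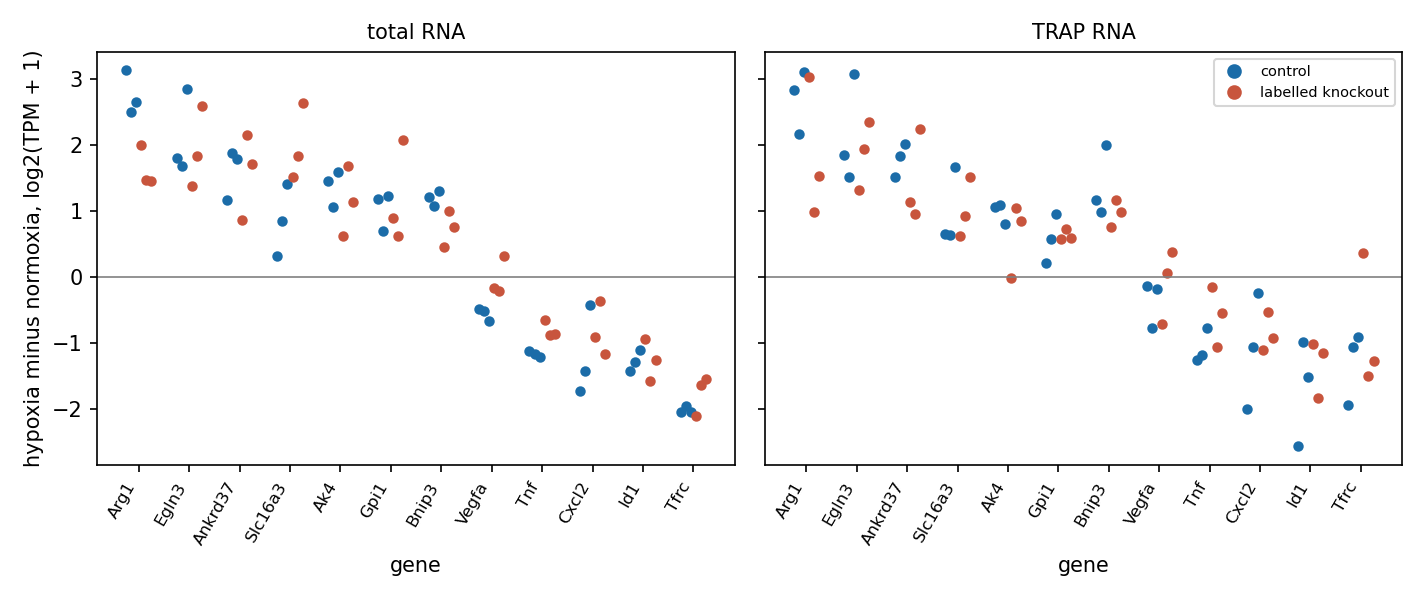
Hypoxia minus normoxia in log2(TPM + 1) (y axis) for 12 genes (x axis) in total RNA and TRAP RNA, 1 point per mouse, controls in blue and labelled knockouts in red. In total RNA Arg1 and Egln3 lay above 0 and Tfrc and Id1 below 0 in 6 of 6 mice, while Vegfa was lower in 5 of 6.

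Glycolysis was the list with the largest share of calls, with all 22 tested genes higher in hypoxia and a median log2 change of 0.61 over the 6 mice. Pgk1 went from 752.5 ± 170.6 to 1266 ± 280.9 TPM (0.75 ± 0.05, limma adjusted p 0.00246) and Eno1 from 385.8 ± 115.3 to 706.9 ± 140.9 TPM (0.90 ± 0.07, adjusted p 0.00489). Pkm and Pgam1 rose by 0.56 ± 0.05 and 0.87 ± 0.08. Of the list, 14 genes passed over all genes and 17 when adjusted over the list alone. Among 30 other HIF-responsive genes, 25 were higher, 13 rose over all genes and 18 when adjusted over the list alone, with a median of 0.41. Fam162a, a mitochondrial protein induced by hypoxia, rose by 0.81 ± 0.09 (adjusted p 0.00997). Vegfa, the angiogenic factor usually counted among these targets, stood at 117.1 ± 63.8 TPM in normoxia and 87.9 ± 38.2 TPM in hypoxia and was not called (-0.28 ± 0.12, adjusted p 0.224). Both directions held under every scaling tried. Camera with an estimated correlation gave each of these lists an adjusted p of 0.145, within 0.112 to 0.276 over the alternatives of the fit. With the preset correlation of 0.01 the adjusted p were 4.77e-17 and 4.14e-12, and fry gave 0.00350 and 0.00407. Leaving out any 1 mouse kept Pgk1, Eno1, Pkm, Pgam1 and Fam162a past the threshold. Without mice HET-129 and KO-301 together, Pgk1 and Eno1 kept their calls and Pkm, Pgam1 and Fam162a lost theirs. Reads of Pgk1, Eno1 and Pgam1 can also match processed pseudogenes, which makes their levels less certain.

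Single genes of the integrated stress and unfolded protein response were called lower in hypoxia, while the list did not pass. Of its 27 genes 3 were higher, with a median of -0.28 under the deposited scaling and the same sign under the others tried. Atf4, the transcription factor at its centre, fell from 717.3 ± 183.9 to 453.1 ± 147.0 TPM (-0.68 ± 0.07, n = 6, limma adjusted p 0.00997). Its targets Ddit3 (-0.50 ± 0.06, adjusted p 0.0138), Asns (-0.66 ± 0.13, adjusted p 0.0391) and Cars (-0.54 ± 0.07, adjusted p 0.0158) fell as well. Over all genes 7 members fell, and 13 fell and 1 rose when adjusted over the list alone. Camera gave the list an adjusted p of 0.145, within 0.112 to 0.966 over its alternatives. Without mouse HET-97 the median of the list was -0.17. Atf4 kept its call whichever mouse was left out and lost it without mice HET-129 and KO-301 together. Ddit3 lost it without HET-97, HET-102 or KO-176 (up to 0.0552), Cars without HET-97 or HET-102 (up to 0.0598) and Asns without any mouse but KO-281 (up to 0.105).

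Single genes of antigen presentation and inflammation were called in hypoxia over the 6 mice, without a list that passed. Cd74, the invariant chain that guards the peptide groove of class II molecules, rose from 107.4 ± 33.9 to 152.7 ± 44.3 TPM (0.51 ± 0.10, n = 6, limma adjusted p 0.0346). The class II genes H2-Aa, H2-Ab1 and H2-DMa rose by 0.42 ± 0.09, 0.49 ± 0.11 and 0.36 ± 0.08, with adjusted p of 0.0463, 0.0476 and 0.0450. These 4 genes were the calls in the list of 9 dendritic cell markers, which held 6 rises when adjusted over the list alone and a camera adjusted p of 0.145. Tnf, the cytokine gene with a known HuR site, fell from 71.4 ± 33.2 to 35.6 ± 16.4 TPM (-0.97 ± 0.09, adjusted p 0.00793), and Osm, another cytokine gene, fell by 0.79 ± 0.15 (adjusted p 0.0382). With Cxcl2 these made 3 falls and 0 rises over all genes among 24 inflammatory cytokines and chemokines, with 7 falls and 3 rises when adjusted over the list alone and a camera adjusted p of 0.538. Among 38 reported HuR targets 3 rose and 4 fell over all genes, and 5 rose and 7 fell when adjusted over the list alone (camera adjusted p 0.496). The matrix protease gene Mmp9 was among the rises (0.88 ± 0.10, adjusted p 0.00997) and Myc among the falls (-0.54 ± 0.08, adjusted p 0.0230). Tnf and Mmp9 kept their calls whichever mouse was left out and lost them without mice HET-129 and KO-301 together. Cd74 lost its call without any mouse but KO-301, H2-Ab1, Cxcl2 and Myc without any but KO-281, and H2-Aa, H2-DMa and Osm without any of the 6, with adjusted p up to 0.130.

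Ribosome-bound RNA gave fewer calls for hypoxia than total RNA, with Egln3 and Ankrd37 named in both. The fit was less precise there, with a median SE of 0.171 against 0.110 in total RNA. Over the 6 mice limma called 3 genes up and 1 down in TRAP RNA of 11676, with 1713 at an unadjusted p under 0.05. In simulated data with 200 changed genes this fit recovered 64 of 100 changed by a log2 of 1 and 90 of 100 changed by 2. It made 15 false calls beside these, which sets no number of false calls among the real ones. Fam162a went from 143.5 ± 32.7 to 290.5 ± 51.9 TPM (1.02 ± 0.10), Egln3 rose by 2.01 ± 0.22 and Ankrd37 by 1.62 ± 0.18. Taf15, an RNA-binding partner of the transcription machinery, fell from 111.2 ± 53.5 to 56.1 ± 19.3 TPM (-0.92 ± 0.10). All 4 had an adjusted p of 0.0451 and moved the same way in 6 of 6 mice, as did 10.2% of all genes tested. Arg1 was at 2.28 ± 0.29, Eno1 at 0.78 ± 0.09 and Pgk1 at 0.76 ± 0.10, each with an adjusted p of 0.0635. Without mouse HET-129 there were 3 calls, and without HET-97, HET-102, KO-176, KO-281 or KO-301 there were 0. Egln3 and Fam162a kept their calls without HET-129 (0.0370 each). Ankrd37 and Taf15 lost theirs whichever mouse was left out (0.0542 to 0.182 and 0.0899 to 0.194). Quantile normalization called 7 genes, and rescaling to nuclear protein-coding genes other than ribosomal proteins called 8. Of the 492 genes called in total RNA, 485 were tested in TRAP RNA and 464 (95.7%) moved in the same direction, against 68.2% of all genes. Both fractions came from the same lysates, so this is not an independent repeat. Rises among the 485 genes had a median of 0.48 in total and 0.46 in TRAP RNA, and falls of -0.42 and -0.37. Fewer calls in TRAP RNA therefore do not show a weaker change. With the oxygen labels of 3 mice swapped in both fractions, 53.8 to 65.6% of as many genes of smallest p agreed over the 10 splits. Of the named falls in total RNA, Rab6a was higher in TRAP RNA of 5 of 6 mice (0.79 ± 0.24, adjusted p 0.226). Malat1 was higher there in 3 of 6 (-0.12 ± 0.45, adjusted p 0.920). These were the labelled knockouts (0.04, 0.34 and 2.31), while Malat1 fell in the controls (-1.38, -1.46 and -0.59). Changes of the labelled genotypes did not overlap for 9.11% of genes in TRAP RNA, where chance gives 10% with 3 against 3. The test of that difference called 0 genes. Arrb1, a named rise, was at 0.26 ± 0.36 (adjusted p 0.765). The direct limma test of a difference between fractions over the 6 mice called 0 genes, with a smallest adjusted p of 0.502. Rab6a, Malat1 and Arrb1 were each at 0.9996, so no such difference was called for them. That fit took the mouse as its block and did not use the pairing of fractions within a lysate. Rab6a, singled out after its values were seen, had a higher change in TRAP than in total RNA in every mouse. Such agreement over the mice, in either direction, held for 4.09% of genes. Across genes, the total and TRAP changes had a Pearson correlation of 0.47, against 0.03 to 0.13 with swapped labels, where genes are not independent replicates.

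The integrated stress list was lower in hypoxic TRAP RNA, with 4 of 27 genes higher, a median of -0.20 and a camera adjusted p of 0.0391. No member passed over all genes and 7 fell when adjusted over the list alone, with Atf4 at -0.61 ± 0.10 (n = 6, limma adjusted p 0.0774) and Asns at -0.51 ± 0.11. The list lost its call without mouse HET-97 (0.115), HET-102 (0.0996), KO-176 (0.118), KO-281 (0.0862) or KO-301 (0.0901) and kept it without HET-129 (0.0432). Both other scalings ended it, at 0.0756 with quantile normalization and 0.0765 with rescaling, within 0.0429 to 0.967 over its alternatives. All 22 glycolysis genes were higher in TRAP RNA, 0 passing over all genes and 15 when adjusted over the list alone. Their camera adjusted p was 0.0989, which became 0.0171 without mouse HET-129, within 0.0148 to 0.310 over its alternatives. Of 28 other HIF-responsive genes 26 were higher, 3 passed over all genes and 16 when adjusted over the list alone, with a camera adjusted p of 0.225.

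Labelled knockout and control macrophages were compared in normoxia to ask which transcripts depend on HuR, and no gene passed in total RNA. Limma gave 0 calls up and 0 down of 12403 genes, with 699 at an unadjusted p under 0.05, 149 higher and 550 lower in labelled knockouts. The median log2 difference of all genes was -0.13 as deposited and -0.11 after rescaling, and the values that follow are read against that shift. The genes given here were chosen from the list of reported HuR targets by their p after the values were seen. Zfp36, which encodes tristetraprolin, a protein that shortens AU-rich messenger RNAs, stood at 794.6 ± 94.7 TPM in controls and 360.1 ± 109.6 TPM in labelled knockouts (-1.18 ± 0.26, n = 3 and 3, adjusted p 0.784). Fos stood at 863.3 ± 147.4 and 329.0 ± 212.6 TPM (-1.56 ± 0.39) and Dusp1, a phosphatase for stress kinases, at 347.2 ± 140.2 and 104.7 ± 1.52 TPM (-1.65 ± 0.45). Vegfa stood at 169.2 ± 24.1 and 65.1 ± 38.1 TPM (-1.59 ± 0.50, and -0.97 without mouse KO-301), and Mmp9 went the other way, at 6.55 ± 3.71 and 24.1 ± 12.4 TPM (1.71 ± 0.55). Each had an adjusted p of 0.784. Of 38 HuR targets 10 were higher and the median was -0.26, with 0 passing over all genes, 2 lower when adjusted over the list alone, and a camera adjusted p of 0.888. Leaving out mouse KO-176 gave 18 calls, 2 up and 16 down, among them Fos at an adjusted p of 0.0407, within 0.0407 to 0.9999 over its alternatives. Without mouse HET-97, KO-281 or KO-301 there was 1 call each, and without HET-102 or HET-129 there were 0. The groups did not overlap for 10.2% of genes, where chance gives 10% with 3 against 3.

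Interferon-stimulated, cholesterol and mitosis genes each leaned one way between the labelled genotypes without passing. Of 33 interferon-stimulated genes, which encode antiviral proteins, 30 were higher in normoxic labelled knockouts (median 0.55), and all 24 genes of cholesterol synthesis and uptake were lower (median -0.83). Of 30 mitosis genes 2 were higher (median -0.40), although camera, which ranks a list against all other genes, gave this list the sign of a rise. These directions held under every scaling tried. For each of the 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone, and camera gave adjusted p of 0.888, 0.888 and 0.924. The mean log2 level of the interferon list in total RNA was 7.07 in control mouse HET-129 and 8.00 in labelled knockout mouse KO-301, against 4.96 and 4.20 in the other controls and 4.92 and 5.38 in the other labelled knockouts. The antiviral gene Isg15 stood at 637.9 and 1986 TPM in normoxic mice HET-129 and KO-301 and between 43.6 and 196.2 TPM in the others. Mki67, a marker of dividing cells, stood at 3.54 and 1.29 TPM in mice HET-129 and KO-301 and between 25.0 and 49.2 TPM in the others. Neutrophil, fibroblast, inflammatory and macrophage lists were also highest in these mice, the macrophage list at 9.18 and 9.06 against 8.58 to 8.90 in the others.

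**Figure D3:**
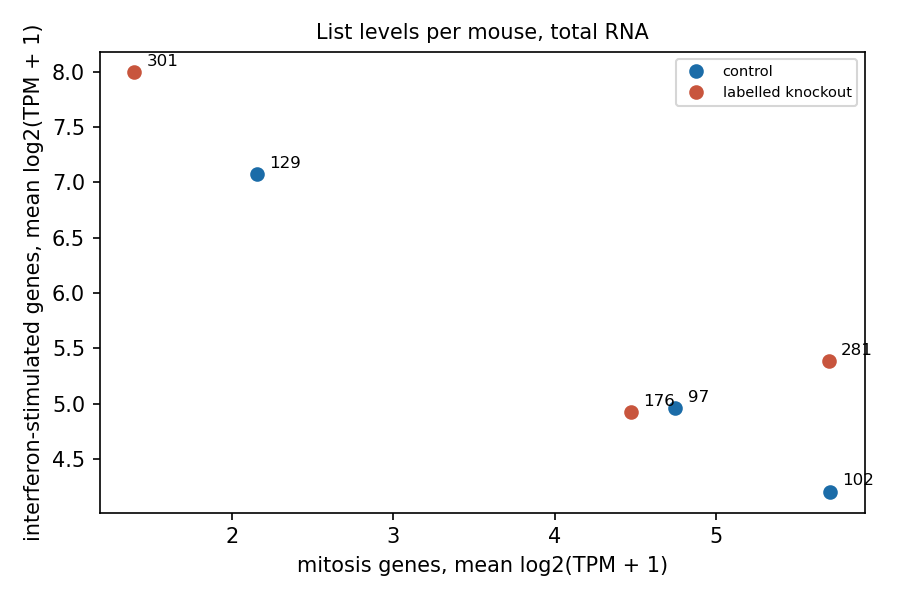
Mean log2(TPM + 1) of the mitosis list (x axis) and of the interferon list (y axis) in total RNA, 1 point per mouse with its number, controls in blue and labelled knockouts in red. Mice HET-129 and KO-301 lay at 7.07 and 8.00 on the interferon axis and at 2.15 and 1.40 on the mitosis axis, apart from the other 4 mice.

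In hypoxia the same comparison gave 0 calls in total RNA by limma, with 430 genes at an unadjusted p under 0.05, 109 higher and 321 lower. Zfp36 stood at 594.4 ± 170.9 TPM in controls and 320.2 ± 62.1 TPM in labelled knockouts (-0.87 ± 0.26, n = 3 and 3), and Osm at 45.9 ± 22.3 and 11.7 ± 4.53 TPM (-1.83 ± 0.45), each with an adjusted p of 0.986. Osm was singled out after its values were seen. Of 38 HuR targets 9 were higher (median -0.22), and of 33 interferon-stimulated genes 32 were higher (median 0.74). In both lists 0 genes passed over all genes and 0 when adjusted over the list alone, with camera adjusted p of 0.940. Leaving out mouse KO-176, KO-281 or KO-301 gave 1 call each. In TRAP RNA the normoxic comparison gave 0 calls of 11676 genes, with 357 at an unadjusted p under 0.05. Leaving out mouse HET-129 or KO-301 gave 1 call there and leaving out KO-176 gave 2. Of 37 HuR targets tested in that fraction 9 were higher (median -0.32), 0 passed over all genes or adjusted over the list alone, and the camera adjusted p was 0.954. The hypoxic TRAP comparison gave 1 call, the unnamed transcript Gm26740, which lies outside the naming rule. It stood at 13.1, 13.6 and 16.8 TPM in controls and 0.921, 1.61 and 1.08 TPM in labelled knockouts (-2.82 ± 0.28, adjusted p 0.00508), with 431 genes at an unadjusted p under 0.05. Its call was lost without mouse HET-97 (0.121), HET-102 (0.199) or KO-281 (0.0538), when only the groups compared were fitted (0.169), and without mice HET-129 and KO-301 together (0.146), within 0.00289 to 0.199 over its alternatives. The number of calls was 2 without mouse HET-129, KO-176 or KO-301.

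No gene passed a test of a difference in the answer to hypoxia between the labelled genotypes, in the planned fit or with the block. Arg1 in total RNA rose from 14.9 ± 6.99 to 114.9 ± 70.1 TPM in controls and stood at 17.2 ± 13.9 and 57.8 ± 43.1 TPM in labelled knockouts, with a difference of the log2 effects of -1.12 ± 1.44 (limma adjusted p 1.00). With the mouse as a block its SE was 0.23 and its adjusted p 0.965. The change per mouse was 3.13, 2.51 and 2.65 in controls and 2.01, 1.47 and 1.45 in labelled knockouts, which did not overlap. Nor did they for 10.2% of genes, where chance gives 10% with 3 against 3. For Slc16a3 the difference was 1.13 ± 0.39, or ± 0.36 with the block, again without overlap, and for Tfrc 0.26 ± 0.61, or ± 0.18 with the block. Both had an adjusted p of 1.00 without and 0.965 with the block. Limma made 0 calls in total RNA with 105 genes at an unadjusted p under 0.05 (574 with the block), at smallest adjusted p of 0.0513 and 0.0690 with the block. In TRAP RNA it made 0 calls with 144 (432 with the block). Leaving out mouse HET-97, rescaling and a pseudocount of 0.1 each gave 1 call in total RNA. No list passed in either fraction, with smallest camera adjusted p of 0.980 and 0.983. The hypoxia effects of controls and labelled knockouts had a Pearson correlation of 0.34 in total RNA and 0.23 in TRAP RNA across genes, which are not independent replicates.

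Ribosome-bound RNA held far less mitochondrial RNA than total RNA in normoxic controls. Transcripts made inside mitochondria are read by mitochondrial ribosomes, which lack L10a. The cytochrome oxidase transcript mt-Co1 stood at 11930 ± 4420 TPM in total RNA and 262.7 ± 264.5 TPM in TRAP RNA (SD, n = 3), a log2 difference of -6.21 ± 0.77 (limma adjusted p 7.44e-05). The transcripts mt-Nd5, mt-Nd2 and mt-Cytb differed by -5.94 ± 0.94, -5.74 ± 1.08 and -5.61 ± 1.02. Among genes higher in TRAP RNA, the ribosomal protein gene Rps20 (chromosome 4, 3831334 to 3835665) stood at 224.2 ± 44.0 and 713.0 ± 38.5 TPM (1.68 ± 0.24, adjusted p 0.000156). The 5S ribosomal RNA gene n-R5s194 (3.30 ± 0.91), Mir6236 (1.60 ± 0.44) and Cdc26, a subunit of the anaphase-promoting complex (1.57 ± 0.56), completed the named rises. Mir6236 bears the name of a microRNA gene and averaged 7140 TPM over the 24 libraries. What its reads come from was not tested. Limma called 4283 of 12918 genes, 3982 of them lower and 7.03% of them higher, with 5728 at an unadjusted p under 0.05, and the median of all genes was -0.60. The block called 689 higher and 6303 lower. The split depended on scaling, with 940 higher and 796 lower after quantile normalization (median -0.007) and 406 higher and 1980 lower after rescaling (median -0.41). Each library was scaled on its own in both tables, so only differences relative to those medians can be read. Without mouse HET-97, HET-102 or HET-129 there were 2929, 2266 and 1832 calls. Mouse HET-129 carried the call of n-R5s194 (0.0967 without it), mice HET-102 and HET-129 that of Mir6236 (0.0529 and 0.0810), and mice HET-102, HET-129 and KO-176 that of Cdc26 (0.261, 0.213 and 0.0551), while Rps20 and the 4 mitochondrial genes kept theirs without any 1 mouse. Other alternatives also ended calls, for n-R5s194 the fits of only the groups compared and without HET-129 and KO-301 together, for Mir6236 quantile normalization, and for Cdc26 the fits without a filter and without both mice. Over all their alternatives the adjusted p ran from 0.00108 to 0.0967, 0.00127 to 0.107 and 0.0143 to 0.261.

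Nuclear-encoded respiratory chain genes passed as a list in TRAP against total RNA in the planned fit and not with the mouse block. Ribosomal protein genes passed as a list with the block and not in the planned fit. Among protein-coding genes, calls higher in TRAP RNA numbered 164, 27, 12 and 4 from the shortest to the longest of 4 equal groups by exon length. List members were not set against genes of like length, so a list difference cannot be told apart from that length trend. Of 60 nuclear-encoded oxidative phosphorylation genes 49 were higher in TRAP RNA (median 0.46), 24 passed over all genes and 25 when adjusted over the list alone. Uqcr10, a subunit of complex III, stood at 432.4 ± 92.2 TPM in total RNA and 1075 ± 106.7 TPM in TRAP RNA (1.33 ± 0.19, n = 3, limma adjusted p 0.000151), and Cox7c, Ndufa3 and Cox6b1 differed by 0.81 ± 0.16, 1.09 ± 0.22 and 0.83 ± 0.17. Their median was 0.59 with quantile normalization and 0.71 with rescaling. Camera gave an adjusted p of 0.0206, which was lost with the mouse block (0.104), with quantile normalization (0.0804), and without mouse HET-97 (0.0631), HET-129 (0.107) or KO-176 (0.0620), within 0.00842 to 0.216 over its alternatives. Of 76 cytosolic ribosomal protein genes 75 were higher (median 0.87), 34 passed over all genes and 43 when adjusted over the list alone. Their median was 0.46 with quantile normalization and 1.12 with rescaling. Their camera adjusted p was 0.344, and 0.0144 with the block. Rpl37a differed by 1.49 ± 0.26 and Rps29 by 1.45 ± 0.26, and since these genes have many near-identical pseudogenes their reads can be split or shared. Of 12 mitochondrially encoded messenger RNAs 10 were lower over all genes and 11 when adjusted over the list alone (median -4.50, camera adjusted p 0.575).

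Lists of messenger RNA decay regulators and of HuR targets were set against the general shift of TRAP RNA, in which 3982 of 12918 genes were called lower, and neither passed. Among protein-coding genes, calls lower in TRAP RNA numbered 245, 841, 1126 and 1604 from the shortest to the longest of 4 equal groups by exon length. Members of these lists were not matched for length either. All 21 AU-rich element RNA-binding protein genes were lower (median -1.09 against -0.60 for all genes), with 13 passing over all genes, 13 when adjusted over the list alone and a camera adjusted p of 0.870. The medians of both lists stayed below 0 under every scaling tried, at -0.56 and -0.46 with quantile normalization. Rc3h1, which encodes the decay factor roquin, differed by -1.60 ± 0.30 (n = 3, limma adjusted p 0.000868). Zfp36l1, a relative of tristetraprolin, differed by -1.90 ± 0.40 and the stress granule protein gene Tia1 by -1.44 ± 0.31. Quantile normalization gave 3 calls in the list, with Rc3h1 at 0.0504 and Tia1 at 0.330, within 3.10e-05 to 0.330 over their alternatives. Zfp36l1 lost its call without mouse HET-129 (0.0578) and Tia1 without HET-102 (0.0582). Of 39 HuR targets 11 were lower over all genes and 11 when adjusted over the list alone (median -0.91, camera adjusted p 0.893), and 4 were with quantile normalization. Among them Sirt1 differed by -1.95 ± 0.26, Mcl1 by -1.28 ± 0.22, Hif1a by -1.88 ± 0.33 and Xiap by -2.65 ± 0.48, each of which kept its call without any 1 mouse. Their values nearest 0 over the alternatives were -1.064, -1.024, -1.121 and -1.905. For Rc3h1, Zfp36l1 and Tia1 these were -0.751, -1.41 and -0.562. The lysosomal genes Asah1 (-1.41 ± 0.25) and Lipa (-1.58 ± 0.33) and the macrophage gene Mpeg1 (-1.52 ± 0.24) were called lower. Their lists did not pass (camera adjusted p 0.893 each), with 13 of 36 and 5 of 25 genes lower over all genes and as many when adjusted over the list alone, beside 3982 of 12918 among all genes.

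**Figure D4:**
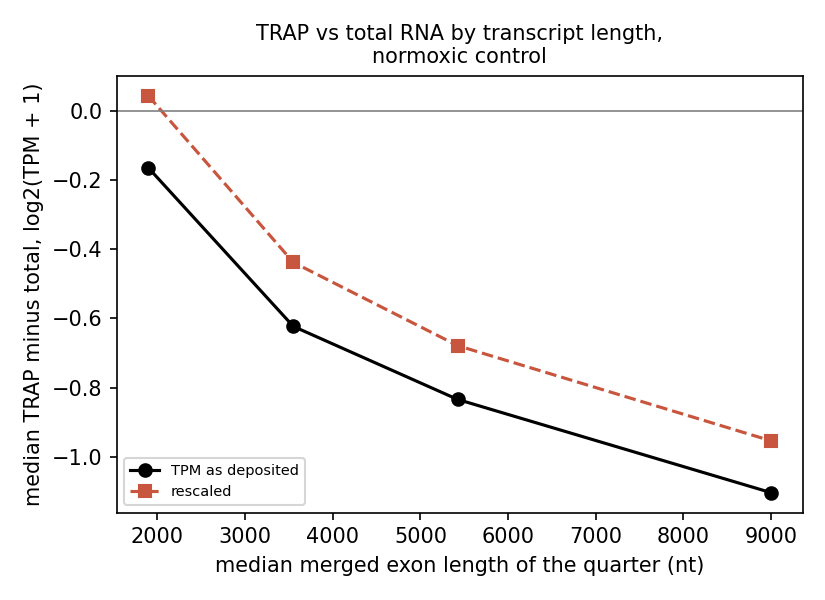
Median log2 difference of TRAP minus total RNA (y axis) against the median merged exon length in nucleotides (x axis) for 4 equal groups by length of 10893 protein-coding genes in normoxic controls, as deposited and after rescaling. The deposited medians were -0.16, -0.62, -0.83 and -1.10 from the shortest to the longest group, and the rescaled ones 0.04, -0.44, -0.68 and -0.95.

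Changes in ribosome-bound RNA beyond those in total RNA were tested as an interaction of fraction with oxygen or genotype, and called 3 transcripts in the planned fits, each near the detection floor. In labelled knockouts the hypoxia effect differed between fractions for the mitochondrial transfer RNA mt-Tc and for Gm22247, each with a limma adjusted p of 0.0228 and with 192 genes at an unadjusted p under 0.05. In normoxia the genotype difference depended on fraction for Gm16265, mt-Tc and Gm22247, each with an adjusted p of 0.0153 and with 196 genes at an unadjusted p under 0.05. Both results share the normoxic labelled knockout libraries. These 3 transcripts lie outside the naming rule and were chosen after their values were seen. Transcript mt-Tc was above 0 in 6 of 24 libraries, at 2.11, 5.76 and 3.55 TPM in normoxic total RNA of labelled knockouts and at 1.02, 2.43 and 2.86 TPM in hypoxic total RNA of controls. Gm22247 was listed above 0 in 3 libraries, at 4.10, 1.61 and 1.70 TPM in normoxic total RNA of labelled knockouts. Both were listed at 0 in all 12 TRAP libraries, so their calls restate values of total RNA and show no change in ribosome-bound RNA. All these calls were lost when only the groups compared were fitted, at adjusted p of 0.545 to 1.00. Without mouse KO-176 the hypoxia interaction gave 3 calls, mt-Tc among them, and without HET-97, HET-102, HET-129, KO-281 or KO-301 it gave 0. The genotype interaction gave 1 call without mouse HET-97 or KO-281, of a transcript other than these 3. It gave 2 without KO-176, mt-Tc among them, and 0 without HET-102, HET-129 or KO-301. In controls limma made 0 calls for the hypoxia interaction (106 at an unadjusted p under 0.05, 329 with the block, and 1 call without mouse HET-97). The genotype interaction in hypoxia gave 0 calls (182), and 1 with the block, Gm16174 with an adjusted p of 0.0458. That transcript reached 1 TPM in 19 of 24 libraries (mean 2.21 TPM) and was listed at 0 in TRAP RNA of all 3 hypoxic labelled knockouts. Over all 6 mice the hypoxia interaction gave 0 calls of 12918 genes, with 401 at an unadjusted p under 0.05 and a smallest camera adjusted p of 0.971.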

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

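Chosen only after the results were seen were the tests of genotype, of sex and of batch labels for mice HET-129 and KO-301, the test of transcript length, the test of the floor by both fractions, and the test of the Elavl1 level.

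Interactions of fraction with oxygen or genotype were called for 3 transcripts near the floor. In labelled knockouts 2 transcripts, mt-Tc and Gm22247, differed in their hypoxia effect, and in normoxia 3 transcripts, these and Gm16265, differed in their genotype effect. All had mean values of at most 0.739 TPM over the 24 libraries and were listed at 0 in most of them. Since mt-Tc and Gm22247 were listed at 0 in all 12 TRAP libraries, their interactions restate total RNA and show no difference in ribosome-bound RNA. Of the 10 splits of the libraries 2 gave as many calls for the hypoxia interaction (2 in the real split, 2 at most in another) and 1 for the genotype interaction (3 in the real split, 1 at most in another), and 10 splits cannot give a share under 0.05.

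Mice HET-129 and KO-301 shared high interferon-stimulated genes and low mitosis genes, although 1 is a control and the other a labelled knockout. Genotype as the whole cause was argued against, since the lowest labelled knockout lay 2.15 log2 units below the highest control on the interferon list (-2.151). Sex was argued against by a range of 3.07 among mice that expressed Eif2s3y, and a few abundant genes by a gap of at least 2.05 that stayed after rescaling. An unrecorded batch or a difference in culture stays open, since 0 samples carried a batch label. A response to interferon in these cultures may have raised these genes, which was not tested.

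Under the deposited scaling most genes stood lower in TRAP than in total RNA of normoxic controls, with a median of -0.60. Quantile normalization, which removes any shift common to all genes, gave -0.007 with 940 calls higher and 796 lower, so the sign for most genes rests on the scaling. Shares of ribosomal protein, mitochondrial and ribosomal RNA that differ between fractions were argued against as the whole cause of the deposited shift. A median of -0.41 remained after rescaling. The smaller mitochondrial share in TRAP RNA would by itself raise the TPM of other genes there. Genes near the floor stay open as a cause. A median of -0.47 among genes above 32 TPM in total RNA decides nothing, since total RNA is 1 side of the difference. Among genes above that level in the mean of both fractions the median was -0.30 as deposited and -0.12 after rescaling, with the mouse nearest 0 at -0.242 and -0.0982. Long transcripts were lower than short ones in all 3 normoxic controls, with Spearman's rho across protein-coding genes of -0.38 or further below 0, where genes are not independent replicates. This is what a loss of long or nuclear-retained transcripts in the purification might give, but a lower ribosome load of long transcripts would give the same order, and no test here parts these. Equal groups of 2720 to 2726 genes by length had medians of -0.16, -0.62, -0.83 and -1.10 as deposited and 0.04, -0.44, -0.68 and -0.95 after rescaling, where the shortest group turned sign.

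Elavl1 was not lower in total RNA of labelled knockouts. Loss of the whole transcript was argued against in normoxic total RNA. The log2 difference less 2 SE was -0.49 there, above the value of -1 set for such a loss. In TRAP RNA the same bound was -2.735 in normoxia and -2.472 in hypoxia, so that fraction cannot decide. A deletion of 1 exon that leaves the transcript in place could give this level, as could incomplete recombination, and values for whole genes cannot part these. The controls carry 1 floxed copy, so their own level may already be reduced, and no mouse with 2 intact copies was analysed here.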

How the results depend on the processing

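TPM hide the depth of each library, so counting error near the detection floor could not be bounded, and planned count-based tests were not run. Rescaling and the removal of mice HET-129 and KO-301 were chosen after seeing the data. Of 1383 values for single genes and lists examined 948 kept their side of the threshold, 428 lost it, 7 gained it and 0 reversed. The count of genes passing, or of lists passing, changed by more than 1.5 times as follows, and the cause was not tested except where fewer mice, genes or residual degrees of freedom were used.

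With quantile normalization, labelled knockout against control in hypoxic total RNA gave 1 call in place of 0, TRAP against total RNA 1736 in place of 4283, the hypoxia interaction with fraction in labelled knockouts 0 in place of 2, the genotype interaction in normoxia 1 in place of 3, and hypoxia over 6 mice in TRAP RNA 7 in place of 4. With rescaling, TRAP against total RNA gave 2386, hypoxia over 6 mice in TRAP RNA 8, the interaction of hypoxia and genotype in total RNA 1 in place of 0, and the lists 1 in place of 2. Without the filter, which adds tested genes, genotype gave 1 in normoxic total, 1 in hypoxic total and 1 in normoxic TRAP RNA, hypoxia 2 in labelled knockout total RNA and 1 in control TRAP RNA, interactions with fraction 3, 5, 6 and 1, and hypoxia over 6 mice 201 in total RNA in place of 492 and 0 in TRAP RNA. A pseudocount of 0.1 gave 1 call each for genotype in normoxic total RNA, hypoxia in labelled knockout total RNA and their interaction, and 0 for hypoxia over 6 mice in TRAP RNA. With only the groups compared, hypoxia in labelled knockout total RNA gave 1, genotype in hypoxic TRAP RNA 0 in place of 1, both interactions with calls 0, and the lists 0. This alternative has no value for interactions of genotype and oxygen within a fraction, nor for hypoxia over 6 mice, where every group of the fraction is already compared.

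With the mouse as a block, which uses the pairing of libraries, hypoxia gave 5 calls in control and 3 in labelled knockout total RNA in place of 0, TRAP against total RNA gave 6992, the genotype interaction with fraction in hypoxia 1, and the lists 1 in place of 2. That 1 list was the ribosomal proteins in TRAP against total RNA, and both lists of the planned fit lost their calls. The block changed no other count of calls by more than 1.5 times. Without the block, hypoxia over 6 mice gave 0 calls in total and 0 in TRAP RNA.

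Leaving out 1 mouse at a time gave from 0 to 18 calls for genotype in normoxic total RNA, 0 to 1 in hypoxic total RNA, 0 to 2 in normoxic TRAP RNA and 0 to 2 in hypoxic TRAP RNA. For hypoxia it gave 0 to 1 in control total, 0 to 2 in labelled knockout total and 0 to 1 in labelled knockout TRAP RNA, and 0 to 1 for their interaction in total RNA. TRAP against total RNA ranged from 1832 to 4766, interactions with fraction from 0 to 1 for hypoxia in controls, 0 to 3 for hypoxia in labelled knockouts and 0 to 2 for genotype in normoxia. Hypoxia over 6 mice ranged from 48 to 224 in total and from 0 to 3 in TRAP RNA, and the lists from 0 to 2. Without mice HET-129 and KO-301, genotype gave 1 in normoxic total, 1 in hypoxic total and 3 in normoxic TRAP RNA, hypoxia 1 in labelled knockout TRAP RNA, the 2 interactions with calls 0, hypoxia over 6 mice 8 in total and 0 in TRAP RNA, and the lists 0. Lists passing numbered 44 with camera's preset correlation and 17 with fry over the 15 planned comparisons, in place of 2. Leaving out X and Y genes kept genotype counts at 0, 0, 0 and 1.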

Other observations

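Named after the results were seen were the lists picked for description here, while the tests of the chromosome 8 interval, of symbol families and of other splits were set before.

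Lists of lysosomal, lipid handling and translation genes did not pass for hypoxia over the 6 mice in total RNA, and each held single calls. Lipa, the lysosomal acid lipase, fell from 570.0 ± 161.4 to 417.4 ± 103.7 TPM (-0.44 ± 0.05, n = 6, limma adjusted p 0.00997), while Lamp1 and Ctsa rose by 0.24 and 0.31. These were 3 of 4 calls among 36 lysosomal genes, with 2 rises and 2 falls both over all genes and adjusted over the list alone, and a camera adjusted p of 0.686. Fabp4, a fatty acid carrier, fell from 140.9 ± 69.0 to 80.6 ± 45.6 TPM (-0.88 ± 0.13, adjusted p 0.0211) and Lpl by 0.51 (adjusted p 0.0420), within 3 falls of 22 lipid genes over all genes and 6 falls and 1 rise adjusted over the list alone (camera adjusted p 0.496). Of 36 translation factors 2 rose and 3 fell over all genes, with 6 each way adjusted over the list alone (camera adjusted p 0.834), among them Eif5b (-0.47 ± 0.06, adjusted p 0.0160) and Eef2 (0.26 ± 0.05, adjusted p 0.0326). Lipa kept its call whichever mouse was left out and lost it without mice HET-129 and KO-301 together. Lamp1, Ctsa, Lpl and Eef2 lost theirs without any of the 6 mice (adjusted p up to 0.111), Fabp4 without HET-97, HET-102, HET-129 or KO-176 (up to 0.0734), and Eif5b without HET-97, HET-102 or KO-176 (up to 0.0651).

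Other lists held few calls in that comparison. Of 60 oxidative phosphorylation genes 26 were higher and 1 fell over all genes and adjusted over the list alone (median -0.02, which turned to 0.003 with quantile normalization), and of 76 ribosomal protein genes 56 were higher and 1 rose, with 0 adjusted over the list alone. All 7 neutrophil markers tested were higher, 0 over all genes and 3 adjusted over the list alone (camera adjusted p 0.155). Cholesterol, interferon, mitosis, DNA replication, mitochondrial and macrophage lists held 0 calls over all genes and 0 adjusted over the list alone, with camera adjusted p of 0.496 to 0.874. Of 37 DNA replication genes 6 were higher (median -0.18) and of 25 macrophage markers 19 were higher (median 0.08). Of lymphocyte markers 3 were tested, and 0 erythroid and 0 mast cell markers reached the filter, too few for a list test.

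A floxed allele brings flanking sequence from the strain it was made in, which may change genes near Elavl1 on chromosome 8. Within 10 Mb, 1 of 57 genes (1.75%) had an unadjusted p under 0.05 between labelled genotypes in normoxic total RNA, against 5.65% elsewhere, with a one-sided Fisher's exact p of 0.964. The bound set for rejecting this was a share at or below that elsewhere, which was met, but the exact 95% interval of 0.0444 to 9.39% includes 5.65%, so the 57 genes were too few to decide. That reading was adopted after the value was seen.

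Genes named by a shared symbol stem were tested as 184 families of at least 8 genes for a joint answer to hypoxia over the 6 mice, and 0 passed in camera, with a smallest adjusted p of 0.886 (Utp and Rbm among the leading families, at medians of -0.24 and -0.14). This bound could not decide either, since the glycolysis list, with 14 of 22 genes called, missed the same threshold at 0.145, a reason found after the value was seen.

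Of 32 splits of the 6 mice between hypoxia and normoxia, the real one gave 492 calls in total RNA, against 0 at most in another. In TRAP RNA the real split gave 4 calls, against 0 at most in another. A share of 1 in 32 is the smallest these splits can give, and the comparisons were added after the data were seen. Chance is therefore not excluded. For the difference between fractions the real split gave 0 calls and another 1 at most. With 0 real calls all 32 splits give as many by necessity, so this count says nothing about chance.

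For comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. Labelled knockout against control in normoxic total RNA gave 0 calls in the real split and 1 at most in another, in hypoxic total RNA 0 and 3, in normoxic TRAP RNA 0 and 3, and in hypoxic TRAP RNA 1 and 1, with 10, 10, 10 and 3 splits as large. Hypoxia against normoxia gave 0 and 1 in control total RNA, 0 and 7 in labelled knockout total RNA, 0 and 2 in control TRAP RNA and 0 and 1 in labelled knockout TRAP RNA, with 10 splits as large each time. The interactions of hypoxia and genotype gave 0 and 1 in each fraction, and those with fraction in controls and for genotype in hypoxia 0 and 2 and 0 and 1, again with 10. TRAP against total RNA gave 4283 in the real split and 2 at most in another, with 1 as large. The 7 calls of another split in hypoxic and normoxic labelled knockout total RNA point to a structure of the samples, since splits that put both libraries of a mouse on the same side reached 7 while the 3 others that part all 3 mice reached 0. Among splits that part all 3 mice, the highest other count was 1 for hypoxia in control TRAP RNA and 0 for TRAP against total RNA.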
